A study of Mus musculus with 20 samples.

How the data were processed

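Gene expression was measured on Affymetrix mouse arrays in heart ventricle, with 20 arrays in the deposited table and 12488 probe sets on each. The deposited values are intensity values on a linear scale, all above 0. Their medians were nearly the same on every array, from 60.74 to 62.45, while the maxima ran from 6092.4 to 6837.2. The summary method, background correction and normalization behind these values are not given in the sources used here. The labels placed 19 arrays in 4 groups: 2 arrays of FVBN control, 4 of FVBN + Doxy, 8 of tTA and 5 of tTA + Doxy. The title of 1 further array, Cardiac tTA expression, gives neither a number nor a treatment, so no group was assigned and it entered no comparison. Arrays are named here by the numbers in their labels. The labels do not state that the arrays come from separate animals, so the p-values measure only the spread between these samples. The number of arrays limits the precision.

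The 66 control probe sets were left out of the tests, which left 12422. A reference table linked 10833 of these to 1 gene and 396 to several, while 1193 carried no gene name; 10817 of the first kind were matched by gene number to a mouse gene table. Intensities were quantile normalized in R 4.3.3 with limma 3.58.1, raised to a floor of 14.37 (the 10th percentile of the normalized values) and put on the log2 scale. The brightest 60% of probe sets by their mean over the 19 arrays were tested, 7453 probe sets for 5658 genes. A linear model with 4 group means was fitted in limma, with the variance moderated along an intensity trend and robustly. Its contrasts gave log2 fold changes, standard errors (SE) and p-values, adjusted by the Benjamini-Hochberg method within each comparison, and a change was called at an adjusted p below 0.05. An array shows the direction of a change when it lies on that side of the mean of the other group. Folds are the exponent of the log2 fold change, not ratios of mean intensities.

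The comparisons were tTA against FVBN control, tTA + Doxy against FVBN + Doxy, FVBN + Doxy against FVBN control, tTA + Doxy against tTA, and the interaction, which is the Doxy effect in tTA minus that in FVBN. The comparisons, tests, threshold, gene lists and rule for named genes were set before the data were examined. The rule named, for each comparison, up to 10 probe sets per direction with the largest called change, among those linked to 1 gene and with a group mean above the median of tested probe sets. It added up to 4 called members with the largest changes from each gene list, and in every comparison Myh6, Myh7, Nppa, Nppb, Acta1, Atp2a2, Pln and Xist. Pln had no probe set linked to it alone and the Xist probe set was too dim to be tested, so neither has a test here. The labels give no sex. Xist read 4.063 on FVBN control array 8182 and 5.153 to 5.979 on the other arrays with a group.

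Gene lists covered pathways and cell types of the ventricle, 35 in all with 943 genes, of which 745 had a probe set linked to them alone. Each gene was represented by its brightest probe set. The 34 lists with at least 5 tested genes, holding 608 different genes, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was run again with the correlation estimated from the data, and fry, which asks whether the genes of a list move on balance one way, was run beside it. Members were also counted with p-values adjusted over the list alone.

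The alternatives set in advance were scaling each array to the same median, no further normalization, other floors, all probe sets, the brightest 40%, array weights, the Xist level as a covariate, leaving out tTA arrays 9310 and 9322, variance moderation without the intensity trend and the robust option, only the arrays compared, each array left out in turn, and the other probe sets of each named gene. Alternatives added after the data were seen were the log2 ratio of the 3' to the 5' beta-actin control probe set as a covariate, leaving out tTA array 7288 and tTA + Doxy array 7399 together, and the lists under each scaling and with each array left out. The beta-actin and Gapdh ratios were compared between groups with exact two-sided permutation tests, adjusted over 4 tests.

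The fit was tested on simulated data with 200 changed probe sets of 7453. Of changes of log2 0.25, it called 52.2% in tTA against FVBN control, 65.7% in tTA + Doxy against FVBN + Doxy, 44.8% in FVBN + Doxy against FVBN control and 74.6% in tTA + Doxy against tTA. Of changes of log2 0.5 it called 95.5%, 95.5%, 86.6% and 97%, and of changes of log2 1 it called 100% in each. The changes were planted with independent noise, 66 or 67 of each size, and the rates hold for that setting alone. Fewer or more variable changes pass less readily. In FVBN + Doxy against FVBN control, Acta1 at 0.83 ± 0.29 did not pass (limma adjusted p = 0.363). Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.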

Results

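Transcript levels were measured in mouse heart ventricle to ask what expression of the tetracycline transactivator (tTA) does to the heart. The tTA protein is a regulator that binds tetracycline operator sequences, and doxycycline (Doxy), a tetracycline antibiotic, prevents this binding. In the heart it is usually driven by the promoter of Myh6, the gene of alpha myosin heavy chain. FVBN is taken here as the FVB/N wild-type strain. Groups held 2 arrays of FVBN control, 4 of FVBN + Doxy, 8 of tTA and 5 of tTA + Doxy. The FVBN arrays are numbered 8177 to 8341, the tTA arrays of both kinds 7288 to 7488, with 9310 and 9322, so no stretch of numbers holds both genotypes and a difference between cohorts cannot be separated from genotype here. Nor do the numbers of arrays with and without Doxy mix within a genotype: FVBN control is 8177 and 8182 against 8337 to 8341 with Doxy, and tTA is 7288 to 7311, 9310 and 9322 against 7399 to 7488 with Doxy. Differences between arrays with and without Doxy are therefore not separated from cohort either. Median deposited intensity lay between 60.74 and 62.45 on every array. Pairs of arrays within a group correlated across probe sets at Pearson r of 0.9865 to 0.9961, and probe sets are not independent replicates. The ratio of the 3' to the 5' beta-actin control probe set, often read as a sign of RNA integrity, differed between genotypes. Its log2 mean was 0.549 ± 0.0085 (SD, n = 2) in FVBN control, 0.509 ± 0.08 (n = 4) in FVBN + Doxy, 0.323 ± 0.11 (n = 8) in tTA and 0.362 ± 0.06 (n = 5) in tTA + Doxy. The 13 tTA arrays lay -0.185 from the 6 FVBN arrays (exact permutation p = 0.00059, adjusted p = 0.00236), and the Gapdh ratio differed by -0.00109 (exact permutation p = 0.974). These control ratios thus disagree as signs of RNA integrity. Acta1, an actin gene, was highest where the beta-actin ratio was lowest in FVBN + Doxy (array 8341, log2 10.39 and 0.407) and tTA + Doxy (7424, 11.43 and 0.27). In FVBN control the array with the lower ratio (8177, 0.543) had the lower Acta1 (9.202). In tTA the lowest ratio was on 7292 (0.145, Acta1 11.04) and the highest Acta1 on 7311 (11.68, ratio 0.227). What moves the ratio was not tested.

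The comparison of tTA with FVBN control asked which transcripts differ when the transgene is present and no Doxy is given. Clu, the gene of clusterin, a secreted chaperone, was 2.21-fold higher in tTA hearts (log2 fold change 1.15 ± 0.09 SE, n = 8 and 2, adjusted p = 2.79e-07, in 8 of 8 tTA arrays). Clu also stands in the list of atrial markers, of which 7 were tested and 2 rose (median 0.0207, camera adjusted p = 0.148). Tpm2, which encodes beta-tropomyosin, rose 3.31-fold (1.73 ± 0.16, adjusted p = 8.55e-06), and Acta1, the skeletal alpha-actin gene, rose 3.20-fold (1.68 ± 0.26, adjusted p = 0.002), each in 8 of 8 arrays. Gstm5, a mu-class glutathione S-transferase gene, had the largest rise among the named genes: 4.2-fold at 1 probe set (2.07 ± 0.29, adjusted p = 0.000631) and 3.60-fold at another (1.85 ± 0.17, adjusted p = 8.21e-06), in 8 of 8 arrays. The other Gstm5 probe sets, with log2 differences of 0.12 and 0.17, did not pass. A further Tpm2 probe set, at -0.059, was too dim to be tested. Ces1d, a carboxylesterase gene, fell most, to a level 3.34-fold lower at 1 probe set (-1.74 ± 0.26, adjusted p = 0.00129, 8 of 8 arrays). Acta2, the smooth muscle alpha-actin gene, was 2.41-fold lower (-1.27 ± 0.20, adjusted p = 0.00151, 8 of 8 arrays).

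Some genes of calcium handling and electrical coupling were lower in tTA hearts, and most members of these lists did not pass. Ryr2, the calcium release channel of the sarcoplasmic reticulum, was 1.76-fold lower (-0.82 ± 0.10, adjusted p = 5.94e-05). Gja1, the main gap junction protein of the ventricle, had a log2 fold change of -0.60 ± 0.07 (adjusted p = 5.94e-05), and both were lower in 8 of 8 arrays. Of 14 tested calcium handling genes, 3 fell and 11 did not pass, with 5 lower when adjusted over the list alone. Ryr2, Slc8a1, the sodium-calcium exchanger (-0.52 ± 0.08), and Cacna1c, the pore of the L-type calcium channel (-0.36 ± 0.08), were those that fell. The list median was -0.0531 (camera adjusted p = 0.00938, and adjusted p = 0.0445 with an estimated correlation). Of 18 ion channel and coupling genes 3 fell, 5 when adjusted over the list alone, with a median of -0.0577 (adjusted p = 0.00938, and adjusted p = 0.0445 with an estimated correlation): Gja1, Cacna1c and Abcc9, a regulatory subunit of potassium channels (-0.66 ± 0.14). Itpr2, an inositol trisphosphate receptor of intracellular calcium stores, fell at 1 probe set (-0.77 ± 0.15), while the brightest stood at -0.24 ± 0.07 (adjusted p = 0.0741) and did not pass, and another, too dim to be tested, at 0.030. Corin, the protease that cleaves the atrial natriuretic peptide precursor, was lower too (-0.78 ± 0.10, adjusted p = 0.000169). Each of these genes was lower in 8 of 8 arrays.

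Lists of mitochondrial genes had medians slightly below 0, by amounts that depend on the scaling (given at the end). Of 59 nuclear genes of oxidative phosphorylation, 6 fell and 53 did not pass, with 10 lower when adjusted over the list alone. The list median was -0.0839 (adjusted p = 2.74e-08, and adjusted p = 0.0445 with an estimated correlation). Cox6a1, a cytochrome oxidase subunit (-0.52 ± 0.08), and Ndufa6, a complex I subunit (-0.38 ± 0.07), were the members that fell most. In the tricarboxylic acid cycle, 2 of 21 genes fell, 6 when adjusted over the list alone, with a median of -0.119 (adjusted p = 0.000103, but adjusted p = 0.226 with an estimated correlation). They were Idh3a (-0.22 ± 0.06) and Sdhb (-0.22 ± 0.05), enzymes of the cycle. In mitochondrial translation, 1 of 43 genes, the ribosomal protein gene Mrps24 (-0.29 ± 0.06), fell, and 4 were lower and 1 higher when adjusted over the list alone (median -0.0863, adjusted p = 2.17e-05, but adjusted p = 0.0571 with an estimated correlation). Of 31 ubiquitin and proteasome genes 0 passed in limma, also 0 when adjusted over the list alone, and 7 had an unadjusted p below 0.05. The list median was -0.0535 (adjusted p = 0.0227, but adjusted p = 0.669 with an estimated correlation). Of 18 endothelial markers 1 fell, Emcn (-0.28 ± 0.07), a surface sialoprotein, and 2 when adjusted over the list alone (median -0.0705, adjusted p = 0.00938, but adjusted p = 0.0571 with an estimated correlation). Of 12 smooth muscle and pericyte markers 2 fell, Acta2 and Abcc9, and 3 when adjusted over the list alone (median -0.0782, adjusted p = 0.0233, but adjusted p = 0.175 with an estimated correlation). The beta-actin ratio was lower on the same tTA arrays, 0.323 against 0.549, and with it as a covariate the smooth muscle list no longer passed (adjusted p = 0.413). Without FVBN control array 8182 the smooth muscle (adjusted p = 0.12), endothelial (0.12) and ion channel (0.0542) lists did not pass. The proteasome list did not pass without FVBN control array 8177 (0.335), and tTA array 7310 also ended its call. Of 19 glycolysis genes 1 rose, Ldha, a lactate dehydrogenase (0.28 ± 0.05), 2 fell, Hk2, a hexokinase (-0.49 ± 0.07), and Ldhb, the partner subunit of Ldha (-0.27 ± 0.06), and 16 did not pass. Adjusted over the list alone 4 were higher and 5 lower, and the list did not pass (median -0.00898, adjusted p = 0.491). Pygb, a glycogen phosphorylase outside that list, fell (-0.77 ± 0.12). Of 14 tested genes of the fetal and hypertrophy list, Acta1 rose, Acta2 fell and 12 did not pass (median -0.101, adjusted p = 0.782). Among genes named in every comparison, Nppb (-0.32 ± 0.27, adjusted p = 0.596), Nppa (-0.10 ± 0.16, adjusted p = 0.806), Myh7 (-0.32 ± 0.24, adjusted p = 0.541) and Atp2a2 (-0.07 ± 0.09, adjusted p = 0.757) did not pass, with 6, 7, 8 and 4 of 8 arrays on the side given. Myh6 was at -0.13 ± 0.06 (adjusted p = 0.266, 7 of 8 arrays).

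In the limma fit 208 probe sets for 182 genes passed, 72 higher and 136 lower in tTA, with a median absolute log2 fold change of 0.316. Of these 37 exceeded 0.5, and 1241 in all had an unadjusted p below 0.05. With each array scaled to the same median 46 were higher and 221 lower. The count was 54 without FVBN control array 8177 and 63 without array 8182, and 27 with the beta-actin ratio as a covariate, which ended 35 of 46 named calls, those of Acta1, Acta2 and Ces1d among them. Clu, Tpm2, Gstm5, Ryr2, Gja1, Corin, Ier3, an early response gene (-0.66 ± 0.09), and Lclat1, a lysocardiolipin acyltransferase (-0.92 ± 0.12), kept their calls under every alternative run on the same probe set.

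**Figure D1:**
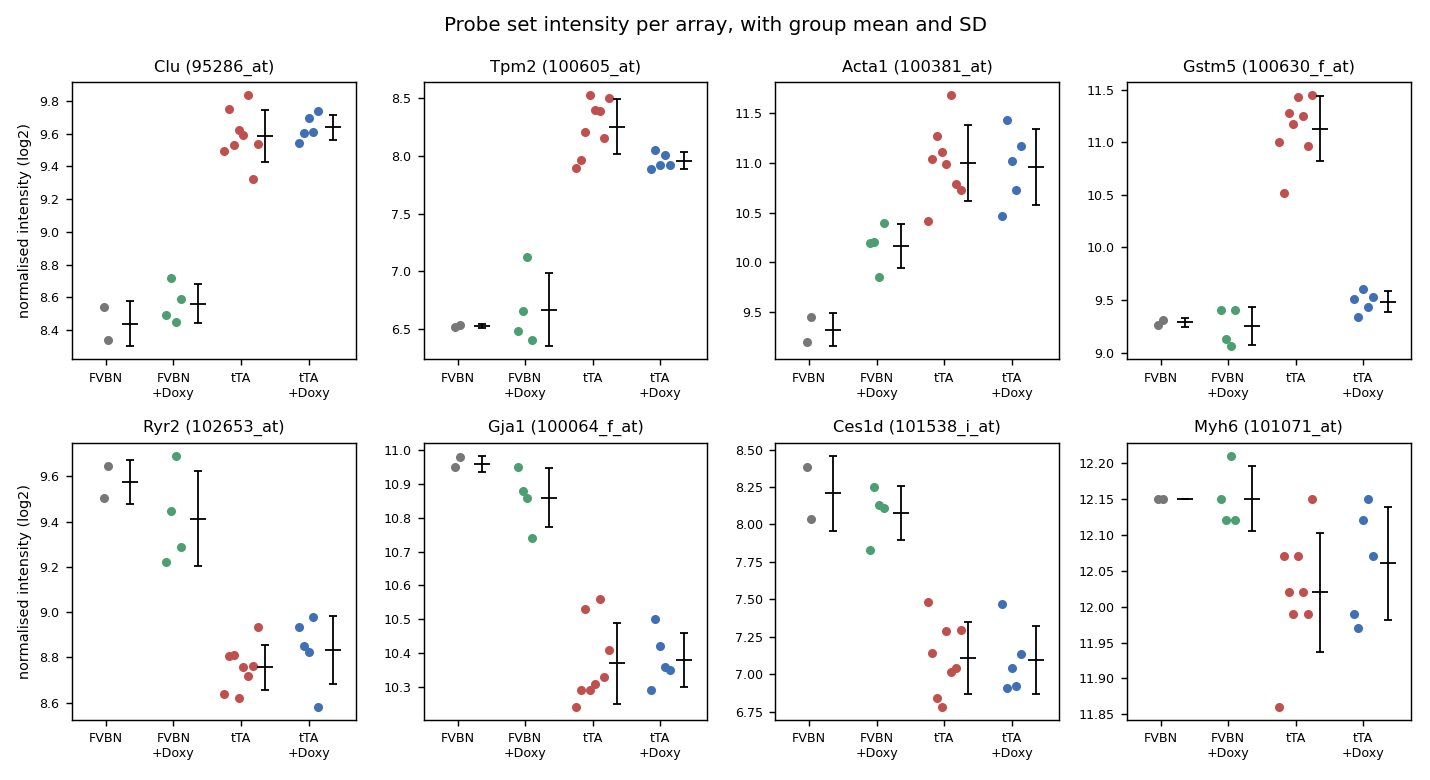
Normalised intensity (log2) of 8 probe sets on each of the 19 arrays, by group, with the group mean and SD beside the points. Clu and Tpm2 sit higher and Ryr2 and Gja1 lower on the tTA arrays with and without Doxy, while Gstm5 at the probe set drawn averages 11.1 in tTA and 9.48 in tTA + Doxy; the vertical axes do not start at 0.

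Under Doxy, the comparison of tTA with FVBN asked which differences are seen when both genotypes receive the drug. Clu was again higher, 2.11-fold (1.08 ± 0.08 SE, n = 5 and 4, adjusted p = 3.94e-08), and Tpm2 was 2.45-fold higher (1.29 ± 0.14, adjusted p = 4.71e-05), each in 5 of 5 tTA + Doxy arrays. Lgals1, the gene of galectin-1, a sugar-binding lectin, rose by 0.65 ± 0.09 on the log2 scale (adjusted p = 0.00026, 5 of 5). Myl9, a regulatory myosin light chain of smooth muscle and other cells, rose (0.53 ± 0.06, adjusted p = 1.75e-05), as did Alad, an enzyme of heme synthesis (0.60 ± 0.11), and Cidea, a lipid droplet protein gene (0.51 ± 0.08), each in 5 of 5 arrays. Lower were Ces1d (-1.39 ± 0.22, adjusted p = 0.00194), Ryr2 (-0.58 ± 0.09, adjusted p = 0.000527), Gja1 (-0.47 ± 0.06, adjusted p = 0.000178) and Ptgds, a prostaglandin D synthase (-1.02 ± 0.25, adjusted p = 0.0252), in 5 of 5 arrays. Nppb, the gene of brain natriuretic peptide, was 1.87-fold lower (-0.90 ± 0.23, adjusted p = 0.0288), and Acta1 1.75-fold higher (0.80 ± 0.22, adjusted p = 0.0461), each in 5 of 5. Gstm5 did not pass (0.60 ± 0.24, adjusted p = 0.168, and 0.23 ± 0.15, adjusted p = 0.38, at the probe sets that rose without Doxy).

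The ubiquitin and proteasome list was higher here at the preset correlation, but not with an estimated correlation (adjusted p = 0.428). In this comparison 6 lists were called at the preset correlation, and other splits of the arrays gave a median of 5. Of 31 tested genes, 4 rose and 27 did not pass, with 6 higher when adjusted over the list alone. The list median was 0.102 (adjusted p = 6.76e-06). Those that rose were Psmd14 (0.23 ± 0.07), Psma5 (0.21 ± 0.05), Psma2 (0.21 ± 0.05) and Psmc2 (0.17 ± 0.04), all subunits of the proteasome. In tTA + Doxy, Psmd14 (7.025 against 7.052) and Psmc2 (7.735 against 7.837) averaged below FVBN control. Psma5 (8.206 against 8.136) and Psma2 (8.97 against 8.925) averaged slightly above it. All of them were lowest in FVBN + Doxy. Of 18 ion channel genes 2 fell, Gja1 and Cacna1c (-0.33 ± 0.07), and 5 when adjusted over the list alone (median -0.0908, adjusted p = 0.00201, and adjusted p = 0.0281 with an estimated correlation). Of 14 calcium handling genes 3 fell, Ryr2, Cacna1c and Slc8a1 (-0.28 ± 0.06), with 4 lower and 1 higher when adjusted over the list alone, and the list itself did not pass (median -0.0323, adjusted p = 0.109). Of 18 fibroblast markers 1 fell, and 3 when adjusted over the list alone (median -0.109, adjusted p = 0.0155, but adjusted p = 0.502 with an estimated correlation). It was Fbln1, a matrix glycoprotein (-0.25 ± 0.07). Of 18 cell cycle genes 2 fell, Mcm3 (-0.24 ± 0.06) and Mcm2 (-0.19 ± 0.05), subunits of the replicative helicase, and 4 when adjusted over the list alone (median -0.0778, adjusted p = 0.0155, but adjusted p = 0.502 with an estimated correlation). The cell cycle list did not pass without FVBN + Doxy array 8337 or tTA + Doxy array 7486 (highest adjusted p = 0.11). The fibroblast list did not pass without 7486 (0.0518) or with the beta-actin ratio as a covariate (0.0719). That ratio was lower on the tTA + Doxy arrays by the same kind of measure (difference -0.147, exact permutation p = 0.0159, adjusted p = 0.0318).

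Oxidative phosphorylation had 1 lower gene of 59, Ndufa6 (-0.22 ± 0.06), and 0 when adjusted over the list alone (median -0.0356, limma camera adjusted p = 0.0496, but adjusted p = 0.502 with an estimated correlation). The tricarboxylic acid cycle had 2 lower genes of 21, Cs, the citrate synthase gene (-0.27 ± 0.07), and Idh3a (-0.19 ± 0.05), with 3 lower and 1 higher when adjusted over the list alone (median -0.077, adjusted p = 0.0496, but adjusted p = 0.502 with an estimated correlation). Neither of these lists passed under the alternative scalings or with the beta-actin ratio as a covariate (adjusted p = 0.217 and 0.231). Leaving out 1 array ended their calls in 9 and 10 of 19 cases (highest adjusted p = 0.162 and 0.164, both without FVBN + Doxy array 8340). In glycolysis 4 of 19 genes rose and 1 fell, with 4 higher and 2 lower when adjusted over the list alone, and the list did not pass (median 0.037, adjusted p = 0.236). Pfkl (0.26 ± 0.06), Tpi1 (0.25 ± 0.06), Ldha (0.24 ± 0.05) and Pgam2 (0.23 ± 0.06), all enzymes of glucose breakdown or lactate formation, rose, and Ldhb (-0.17) fell. In mitochondrial translation 4 of 43 genes rose, also 4 when adjusted over the list alone, and the list did not pass (median 0.0279, adjusted p = 0.164). Mrps25 (0.45 ± 0.10), Mrps10 (0.36 ± 0.07) and Mrpl27 (0.32 ± 0.05), mitochondrial ribosomal protein genes, were among them. Mrps25 averaged 7.1 in tTA + Doxy and 7.097 in FVBN control, against 6.651 in FVBN + Doxy, so its difference lay in low FVBN + Doxy arrays. In the same order Mrps10 averaged 6.738, 6.652 and 6.375, and Mrpl27 8.119, 7.899 and 7.797. Among sarcomere genes 1 of 17 rose, Mybpc3, the cardiac myosin binding protein (0.31 ± 0.05), 1 when adjusted over the list alone (median 0.0151, adjusted p = 0.794). Nppa stood at -0.30 ± 0.13 (adjusted p = 0.2, 5 of 5 arrays), Myh6 at -0.09 ± 0.05 (adjusted p = 0.312, 4 of 5), Myh7 at -0.03 ± 0.21 (adjusted p = 0.945, 3 of 5) and Atp2a2 at -0.07 ± 0.08 (adjusted p = 0.63, 3 of 5), none of them past the threshold.

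In this comparison 437 probe sets for 384 genes passed in limma, 318 higher and 119 lower, with a median absolute log2 fold change of 0.253. Of these 30 exceeded 0.5, and 1575 in all had an unadjusted p below 0.05. The count was 271 without FVBN + Doxy array 8337, 241 without 8341, 271 without tTA + Doxy array 7485, 267 without 7488, 282 with all probe sets and 703 with array weights. Of 63 named calls, 31 held under every alternative on the same probe set, Clu, Tpm2, Ryr2, Gja1, Ces1d, Lgals1 and Myl9 among them, while those of Acta1, Nppb, Acta2 (-0.66 ± 0.17) and Ptgds ended under several.

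The effects of tTA with and without Doxy rest on different arrays and could be compared gene by gene. Of the called genes, 22 were higher in both comparisons, where 2.96 would be shared if calls were independent, and 41 were lower in both, where 1.99 would be. Genes with a small pooled spread pass more readily in both, so these chance figures may be too low. In opposite directions 0 genes were called. Clu, Tpm2, Acta1, Lgals1, Gnb3, a G protein subunit (0.71 ± 0.13 without and 0.59 ± 0.11 with Doxy), and Pdlim1, a cytoskeletal adaptor (0.55 and 0.51), were among the higher. Ces1d, Acta2, Ryr2, Gja1, Slc8a1, Cacna1c, Lclat1, Pygb, Corin (-0.78 and -0.40) and Oxct1, which starts ketone body use (-0.55 and -0.45), were among the lower. Oxct1 was picked after its values were seen. The median ratio of the change with Doxy to that without was 0.806 over the shared genes. Standard errors were larger without Doxy (median 0.0671 against 0.0569), so genes needed larger estimates to pass there. This selection alone can put the ratio below 1, and a weaker effect under Doxy cannot be read from it. Across 5658 genes the log2 fold changes correlated at Pearson r = 0.388 and Spearman rho = 0.178, and genes are not independent replicates. Leaving out 1 array moved r between 0.275 and 0.429, and r was 0.172 with the Xist level as a covariate, which stands lowest on FVBN control array 8182 (4.063); the labels give no sex.

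**Figure D2:**
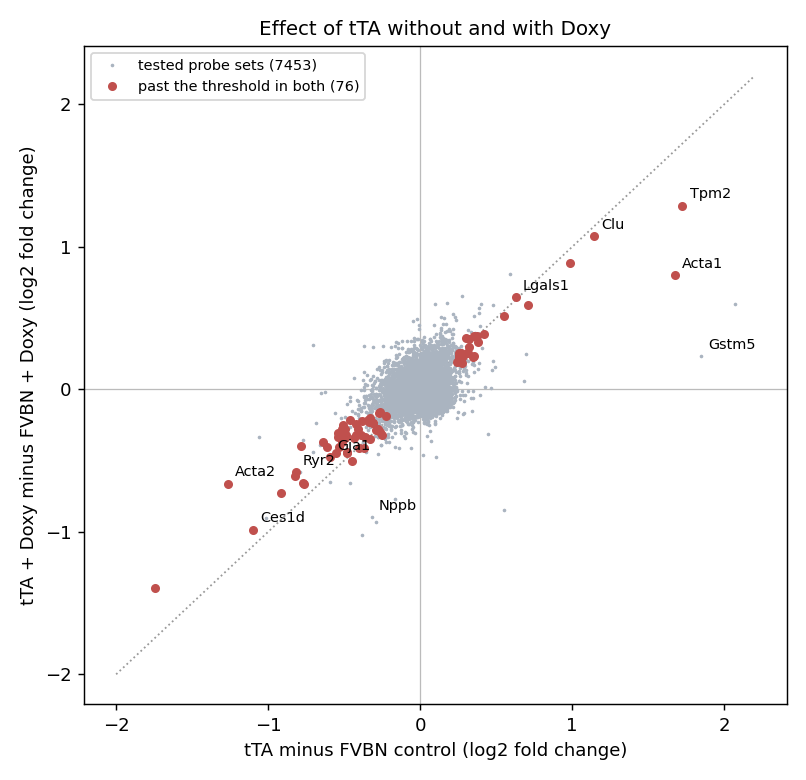
Log2 fold change of tTA against FVBN without Doxy (horizontal) and with Doxy (vertical) for 7453 probe sets, with a dotted line of equal change. The 76 probe sets past the threshold in both, shown larger, all have the same sign in each, and Gstm5, at the probe set marked, lies far to the right at 1.85 without Doxy and 0.23 with Doxy.

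Doxy in FVBN hearts, compared with FVBN control, asked which transcripts differ with the drug when the transgene is absent. Nampt, the enzyme of NAD salvage, was 1.75-fold lower (-0.80 ± 0.10 SE, n = 4 and 2, adjusted p = 0.000371, 4 of 4 arrays). Cdkn1a, an inhibitor of the cell cycle, was 1.5-fold higher (0.59 ± 0.10, adjusted p = 0.0284), and Gon4l, a nuclear protein gene, 1.30-fold higher (0.38 ± 0.07, adjusted p = 0.035), each in 4 of 4. Cdkn1a and Gon4l lost their calls under the median scaling (adjusted p = 0.0616 and 0.0812), with all probe sets (0.125 and 0.113), with only the arrays compared (0.0991 and 0.211), and without FVBN control array 8177 or 8182 or FVBN + Doxy array 8338 or 8340. Gon4l also lost its call with no further normalization (0.0691), without tTA array 7294, 7308, 7310 or 9310 and without tTA + Doxy array 7485 (0.0529 to 0.0595). Another Cdkn1a probe set, at 0.23, did not pass. Nampt lost its call without FVBN control array 8177 (0.0789). Of the genes named in every comparison, Acta1 stood at 0.83 ± 0.29 (adjusted p = 0.363, 4 of 4 arrays), Nppb at 0.60 ± 0.29 (adjusted p = 0.439, 4 of 4) and Myh7 at -0.29 ± 0.27 (adjusted p = 0.67, 3 of 4). Nppa stood at 0.12 ± 0.17 (adjusted p = 0.8, 3 of 4), Atp2a2 at -0.01 ± 0.10 (adjusted p = 0.966, 2 of 4) and Myh6 at -0.00072 ± 0.065 (adjusted p = 0.996, 2 of 4).

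At the preset correlation 7 lists were called under Doxy in FVBN hearts, although 0 of their members passed in limma. Of these 7 lists, 0 held with an estimated correlation or with fry. Examples here and in the next comparison were chosen after their values were seen. The ubiquitin and proteasome list was lower (median -0.123, adjusted p = 1.94e-05, but adjusted p = 0.344 with an estimated correlation): 12 of 31 members, all lower, had an unadjusted p below 0.05 and 2 passed adjusted over the list alone. Psmc2, a subunit of the regulatory particle, stood at -0.27 ± 0.06. Mitochondrial translation (median -0.0752, adjusted p = 0.00118, but adjusted p = 0.344 with an estimated correlation) and oxidative phosphorylation (median -0.0466, adjusted p = 0.0309, but adjusted p = 0.539 with an estimated correlation) were lower, with 8 of 43 and 2 of 59 members at an unadjusted p below 0.05 and 0 adjusted over the list alone. The circadian list was lower (median -0.108, adjusted p = 0.0309, but adjusted p = 0.586 with an estimated correlation), with 3 members lower and 1 higher adjusted over the list alone. Dbp and Nr1d2, clock output and repressor genes, stood at -0.85 ± 0.31 and -0.76 ± 0.20. Endothelial markers were lower (median -0.0796, adjusted p = 0.0309, but adjusted p = 0.344 with an estimated correlation), with 1 lower adjusted over the list alone. Immediate early genes were higher (median 0.0982, adjusted p = 0.0309, but adjusted p = 0.586 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. Egr1, a growth response regulator, stood at 0.45 ± 0.10. Erythroid genes were higher, 8 of 8 of them (median 0.126, adjusted p = 0.0309, but adjusted p = 0.348 with an estimated correlation), with 1 adjusted over the list alone.

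In all 3 probe sets passed under Doxy in FVBN hearts, 2 higher and 1 lower, and 881 had an unadjusted p below 0.05. The count was 1 without FVBN control array 8177, 1 without FVBN + Doxy array 8338, 7 without tTA array 9322 and 13 with the Xist level as a covariate. The list count was 4 without FVBN control array 8177, where the circadian (adjusted p = 0.116), immediate early (0.332), mitochondrial translation (0.0586) and oxidative phosphorylation (0.0839) lists did not pass. Without array 8182 the endothelial (0.244) and erythroid (0.24) lists did not pass. FVBN + Doxy arrays 8337, 8338, 8340 and 8341 each ended at least 1 list call, and the proteasome list kept its call without each array.

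Doxy in tTA hearts, compared with tTA alone, asked which transcripts differ with the drug when the transgene is present. Gstm5 fell, to a level 3.45-fold lower at 1 probe set (-1.79 ± 0.21 SE, n = 5 and 8, adjusted p = 0.000893) and 3.14-fold lower at another (-1.65 ± 0.12, adjusted p = 1.17e-06), each in 5 of 5 tTA + Doxy arrays. On the latter probe set the group means were 9.29 in FVBN control, 9.25 in FVBN + Doxy, 11.1 in tTA and 9.48 in tTA + Doxy. The other Gstm5 probe sets stood at 0.013 and -0.22 and did not pass. Mrpl20, a mitochondrial ribosomal protein gene, was higher (0.31 ± 0.05, adjusted p = 0.00584), as was Myl9 (0.29 ± 0.05, adjusted p = 0.0139), each in 5 of 5. Ccdc58, a dim transcript outside the naming rule and chosen after its values were seen, was higher by 0.28 ± 0.05 (adjusted p = 0.0211). Of the shared genes above, chosen here after their values were seen, Clu (0.05 ± 0.07, adjusted p = 0.906), Tpm2 (-0.29 ± 0.12, adjusted p = 0.563), Ryr2 (0.08 ± 0.07, adjusted p = 0.865), Gja1 (0.01 ± 0.05, adjusted p = 0.97) and Ces1d (-0.11 ± 0.19, adjusted p = 0.932) were not called. The genes named in every comparison were not called either: Acta1 stood at -0.04 ± 0.19 (adjusted p = 0.98, 2 of 5 arrays on that side), Nppb at 0.02 ± 0.19 (0.988, 2 of 5), Nppa at -0.08 ± 0.11 (0.907, 3 of 5) and Myh6 at 0.04 ± 0.04 (0.88, 3 of 5). Myh7 at 0.0013 ± 0.18 (0.998, 3 of 5) and Atp2a2 at -0.01 ± 0.06 (0.981, 2 of 5) were likewise not called.

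At the preset correlation 7 lists were higher under Doxy in tTA hearts, and 0 of these 7 held with an estimated correlation or with fry. In other splits of the same arrays the median number of called lists was 4, so this count does not stand apart from chance. In mitochondrial translation 1 of 43 genes rose, Mrpl20, and 4 adjusted over the list alone (median 0.0373, adjusted p = 1.38e-05, but adjusted p = 0.236 with an estimated correlation). Of 31 ubiquitin and proteasome genes 0 passed in limma, 6 had an unadjusted p below 0.05 and 1 passed adjusted over the list alone (median 0.0506, adjusted p = 1.13e-05, but adjusted p = 0.312 with an estimated correlation). Of 18 heat shock and chaperone genes 0 passed, 3 had an unadjusted p below 0.05 and 2 passed adjusted over the list alone (median 0.089, adjusted p = 0.00119, but adjusted p = 0.383 with an estimated correlation). Dnajb1, a cochaperone, stood at 0.36 ± 0.11. Of 15 metallothionein and glucocorticoid response genes 0 passed, 4 had an unadjusted p below 0.05 and 3 passed adjusted over the list alone (median 0.0846, adjusted p = 0.00759, but adjusted p = 0.281 with an estimated correlation). Mt1, a metal-binding metallothionein, stood at 0.26 ± 0.05. Of 19 glycolysis genes 0 passed, 4 had an unadjusted p below 0.05 and the same number passed adjusted over the list alone (median 0.033, adjusted p = 0.0126, but adjusted p = 0.511 with an estimated correlation). Macrophage markers (14 tested, median 0.0651, adjusted p = 0.00759, but adjusted p = 0.597 with an estimated correlation) and interferon response genes (15 tested, median 0.0245, adjusted p = 0.0104, but adjusted p = 0.597 with an estimated correlation) had 0 called members, 6 and 5 at an unadjusted p below 0.05 and 0 adjusted over the list alone. B2m, the light chain of class I antigen presentation, stood at 0.62 ± 0.20.

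In limma 5 probe sets passed, 3 higher and 2 lower, and 570 had an unadjusted p below 0.05. The count was 23 without tTA array 7294, 3 without tTA + Doxy array 7399, 2 with all probe sets and 11 with array weights, and the list count was 3 without tTA + Doxy array 7424. Without that array the heat shock (adjusted p = 0.115), macrophage (0.136) and metallothionein (0.0725) lists did not pass, nor did the interferon list, whose highest value was 0.228 without tTA array 7294. Macrophage markers also lost their call without 7294, and both of these lists without tTA + Doxy array 7399. The interferon list lost it without tTA array 7311, and glycolysis without 7311 or tTA + Doxy array 7486 (highest 0.0691). Mitochondrial translation and the proteasome list kept their calls without each array. Mrpl20 lost its call with all probe sets (adjusted p = 0.0515) and without tTA array 7288 and tTA + Doxy array 7399 (0.0721). Myl9 lost its call with all probe sets (0.0845), without that pair of arrays (0.116), without 7399 alone (0.0628) and without tTA arrays 9310 and 9322 (0.0575). Gstm5 kept its calls under every alternative on the same probe set.

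The interaction asked whether the difference between arrays with and without Doxy depends on tTA. Gstm5 was the gene called: its Doxy effect in tTA minus that in FVBN was -1.61 ± 0.23 at 1 probe set (adjusted p = 0.0108), where every tTA + Doxy array lay below the tTA mean. The other probe set that fell under Doxy in tTA, at -1.48 ± 0.38, did not pass (adjusted p = 0.193). The single call ended without FVBN control array 8177 (adjusted p = 0.141) or 8182 (0.0966), with all probe sets (0.0569), with the Xist level as a covariate (0.0666) and without tTA array 7288 and tTA + Doxy array 7399 (0.051). Acta1 stood at -0.87 ± 0.35 (adjusted p = 0.296), Nppb at -0.58 ± 0.35 (0.443), Myh7 at 0.29 ± 0.32 (0.676), Nppa at -0.20 ± 0.21 (0.656) and Myh6 at 0.04 ± 0.08 (0.819), and Atp2a2 at -0.00084 ± 0.12 (0.999), so no difference between the Doxy effects was called for them. Ubiquitin and proteasome genes were higher by this measure (31 tested, median 0.178, adjusted p = 1.59e-08, but adjusted p = 0.159 with an estimated correlation), with 0 members called, 13 at an unadjusted p below 0.05 and 6 adjusted over the list alone. Mitochondrial translation (median 0.134, adjusted p = 7.1e-07, but adjusted p = 0.115 with an estimated correlation) had 0 of 43 called, 13 at an unadjusted p below 0.05 and 2 adjusted over the list alone. Oxidative phosphorylation (median 0.044, adjusted p = 0.0154, but adjusted p = 0.694 with an estimated correlation) had 0 of 59 called, 6 at an unadjusted p below 0.05 and 0 adjusted over the list alone. In limma 1 probe set passed and 1088 had an unadjusted p below 0.05, with a count of 3 without FVBN + Doxy array 8340, 4 without tTA array 7311, 3 without tTA array 9322 and 2 without tTA + Doxy array 7424. The Doxy effects in tTA and FVBN correlated across 5658 genes at Pearson r = -0.113 and Spearman rho = -0.252. Without tTA + Doxy array 7424 this r was -0.213 and without array 7486 it was -0.0435, the lowest and highest with 1 array left out.

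**Figure D3:**
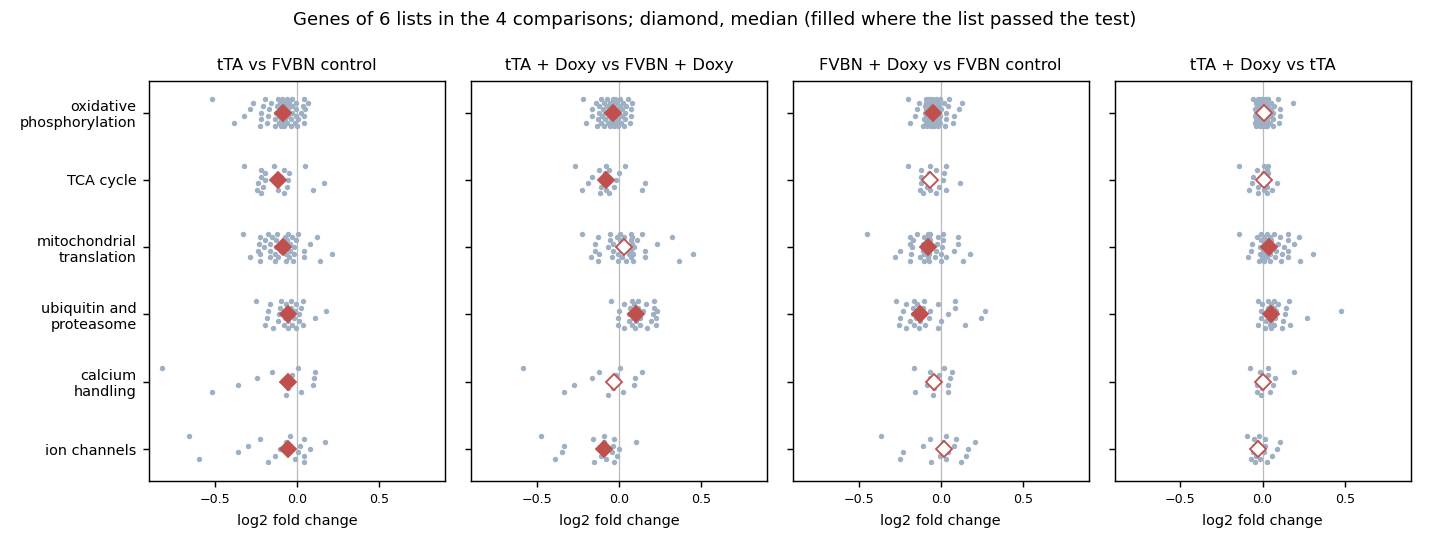
Log2 fold change of each tested gene (points) of 6 lists in 4 comparisons, with the list median as a diamond, filled where the list passed at the preset correlation. The ubiquitin and proteasome median is -0.123 in FVBN + Doxy against FVBN control and 0.102 in tTA + Doxy against FVBN + Doxy. Both comparisons use the same FVBN + Doxy arrays, with opposite sign.

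Among all lists called, those that held with an estimated correlation were oxidative phosphorylation, calcium handling and ion channels in tTA against FVBN control, and ion channels in tTA + Doxy against FVBN + Doxy. Every called list kept the direction of its median and its test under both alternative scalings, which moved the median of all tested genes by no more than log2 0.0169 from 0. Sizes moved more, here first with the median scaling and then with no further normalization. Oxidative phosphorylation went from -0.0839 to -0.208 and -0.194 in tTA against FVBN control, from -0.0466 to -0.127 and -0.115 in FVBN + Doxy against FVBN control, from 0.044 to 0.184 and 0.162 in the interaction, and from -0.0356 to -0.0234 and -0.0301 in tTA + Doxy against FVBN + Doxy. In tTA against FVBN control the tricarboxylic acid cycle went from -0.119 to -0.234 and -0.219, calcium handling from -0.0531 to -0.129 and -0.114, and the proteasome list from -0.0535 to -0.105 and -0.0903. In the interaction the proteasome list went from 0.178 to 0.271 and 0.25, and under Doxy in tTA from 0.0506 to 0.0803 and 0.0706, with glycolysis there from 0.033 to 0.0587 and 0.0491. For the called lists the median, mean and test had the same sign. They differed in sign in lists that were not called, such as extracellular matrix in tTA against FVBN control (median 0.0198, mean -0.00441) and fatty acid oxidation (median -0.0286, mean 0.00711).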

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

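Chosen only after the result was seen were the tests of drift along the array numbers, of Gstm relatives and processing for Gstm5, of the FVBN control arrays for the proteasome list, and of a chromosomal segment; the test of RNA integrity was added after the beta-actin ratio was seen to differ but before its own result, and the counts of other splits were set before.

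The first pattern is the set of 76 probe sets that passed in both comparisons of tTA with FVBN, 28 higher and 48 lower, with 0 in opposite directions. A difference in RNA integrity between the genotypes would remove these changes with the beta-actin ratio as a covariate, if that ratio measured it closely. Instead the log2 fold changes kept a median of 0.904 of their size without Doxy (quartiles 0.791 and 1.02) and 0.924 with Doxy (0.832 and 1.02), and 76 of 76 kept their sign. This argues against it as the whole cause, as far as this ratio measures it, although only 20 and 47 of the 76 remained past the threshold. The median absolute log2 fold change was 0.407 before and 0.375 after without Doxy, and 0.327 and 0.303 with Doxy. The median standard error of a single probe set was 0.0762 before and 0.0993 after without Doxy, and 0.0646 and 0.0769 with Doxy. The larger errors alone would leave 31 and 48 calls, the smaller effects alone 62 and 68. A steady drift along the array numbers would put tTA arrays 9310 and 9322 on the other side of the FVBN control arrays; over the 437 probe sets called under Doxy, and in the direction seen there, their median shifts from each single control array were 0.0501 to 0.136, against 0.0338 between the control arrays, which argues against it. A chromosomal segment carried along with the transgene would put shared genes side by side; 1 neighbouring pair was found against 0.374 in shuffled orders (one-sided permutation p = 0.312), and the larger sets differ, with 6 pairs against 2.93 (p = 0.0762) without Doxy and 9 against 14.5 (p = 0.959) with Doxy, so this stays undecided. An effect of the transgene, which the groups name, may underlie the pattern and remains a hypothesis, and so does a difference between cohorts, since no array of the other genotype shares the numbers of either.

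The next pattern is Gstm5, whose Doxy effect in tTA minus that in FVBN was -1.61 on the log2 scale at 1 probe set (adjusted p = 0.0108), a call that ended without FVBN control array 8177 (0.141) or 8182 (0.0966), with all probe sets (0.0569), with the Xist level (0.0666) and without tTA 7288 and tTA + Doxy 7399 (0.051), and that was not made at the other probe set that fell (-1.48, adjusted p = 0.193). Transcripts of Gstm1, Gstm2, Gstm3 or Gstm6 binding to its probes would fall too, but the lowest change among their probe sets under Doxy in tTA was -0.0607, against -1.65 for Gstm5 itself, which argues against them. A processing difference of the tTA + Doxy arrays would move other probe sets as far, but the largest other change was 0.738 (Wdr92, adjusted p = 0.3). The Gstm5 probe sets disagree among themselves, with 0.0134 and -0.223 at those that did not pass, and Gstm relatives without a probe set of their own were not analysed here. An effect of Doxy that depends on tTA may underlie the pattern, since the groups name both, and remains a hypothesis.

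The last pattern is in the lists whose Doxy effect differed between tTA and FVBN by camera: ubiquitin and proteasome (median difference 0.178), mitochondrial translation (0.134) and oxidative phosphorylation (0.044). If only the 2 FVBN control arrays stood apart, the proteasome list would not differ between the genotypes under Doxy, where they play no part. There it was higher at the preset correlation (adjusted p = 6.76e-06) but not with the estimated correlation (adjusted p = 0.428), so a shift of the control arrays cannot be told apart from an effect of Doxy with tTA. The FVBN + Doxy arrays enter this comparison (median 0.102) and that with FVBN control (-0.123) with opposite sign. Low values on those arrays alone would move both and the interaction, and this was not tested. The comparison of tTA + Doxy with tTA, which leaves them out, had a median of 0.0506. Leaving out either control array kept all 3 of these list calls at the preset correlation, which cannot test whether both control arrays stand apart together. A response to Doxy that differs with tTA may exist, and these arrays leave it open, since array numbers with and without Doxy do not mix either.

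Of 100 splits drawn from the 126 possible ones of the tTA + Doxy and FVBN + Doxy arrays, 1 gave at least 437 probe sets, the real one itself. The highest other gave 232, which argues against chance as the source of that count. For the 6 lists of that comparison 44 of 100 splits gave as many, and the others had a median of 5 and up to 12, so chance cannot be excluded. For tTA + Doxy against tTA 2 of 100 drawn from 1287 splits, the real one included, gave at least 5 probe sets, and the median of the others was 0. A count of 5 or more was thus rare among the splits drawn, but chance cannot be excluded, since 1 other split gave far more. That split, the highest of the others, gave 191, with tTA arrays 7294, 7311 and 9322 beside tTA + Doxy arrays 7485 and 7486. Whether the samples hold a structure that the groups do not follow was not tested. For the 7 lists of tTA + Doxy against tTA 21 of 100 splits gave as many, and the others had a median of 4 and up to 11, so chance cannot be excluded.

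Single arrays far from the others of their group were found in 14 of 285 tests, where chance gives about 1 in 20, or 14.2. The gap to the nearest array as a share of the group range was 0.883 for Perp in FVBN + Doxy array 8341 and 0.902 for Mcm3 in FVBN + Doxy array 8337. Among tTA arrays it was 0.658 for Nppa in 9310, 0.698 for Tnnt1 and 0.547 for Ifi35 in 7288, 0.53 for Hk2 and 0.623 for Mcm2 in 7311, 0.602 for Sdhb in 7292, and 0.66 for Cidea in 7308. Among tTA + Doxy arrays it was 0.735 for Clu, 0.746 for Hspa9, 0.733 for Nr1d1 and 0.818 for Cidea in 7486, and 0.716 for Tpi1 in 7424. Array 7486 held 4 of the 14.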

How the results depend on the processing

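The alternatives chosen after the data were seen were the beta-actin ratio as a covariate, leaving out tTA array 7288 with tTA + Doxy array 7399, the lists under each scaling and with each array left out, and all alternatives of the correlations across genes. No named call reversed on its own probe set; 10 of 46, 31 of 63, 0 of 3, 2 of 4 and 0 of 1 named calls, in the order of the comparisons in the report, held under all alternatives on that probe set. Most calls that ended in tTA against FVBN control ended with the beta-actin ratio (35 of 46), all probe sets (11), or without FVBN control array 8177 (27) or 8182 (21), and no other single array ended more than 3. Under Doxy the ratio ended 24 of 63 and all probe sets 21, and single arrays ended up to 22 (FVBN + Doxy array 8340). With all probe sets more tests are adjusted for; for the ratio, larger standard errors ended more calls than smaller effects did among the probe sets called in both comparisons of tTA with FVBN (above). For the other settings the cause was not tested. Where FVBN control is left with 1 array, the fit pools the spread, and the lone sample is assumed to vary like the other groups. No paired analysis was possible because the groups differ in the number of arrays and no label pairs them. The floors changed no call, which says nothing, since no tested probe set lies near them. The fit to only the arrays compared was not run for the interaction. Signal over background limits what can be seen: the dimmest tested probe set averaged 5.468 on the log2 scale.

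The count for tTA against FVBN control, 208 (72 higher, 136 lower), was 27 with the beta-actin ratio, and 46 higher with 221 lower with the median scaling. For tTA + Doxy against FVBN + Doxy, 437, it was 282 with all probe sets and 703 with array weights. For FVBN + Doxy against FVBN control, 3 (2 higher, 1 lower), it was 0 higher and 2 lower with the median scaling, 1 higher and 2 lower with no further normalization, 1 with all probe sets, 13 with the Xist level, 8 without tTA 9310 and 9322, 5 without tTA 7288 and tTA + Doxy 7399, and 5 with only the arrays compared. For tTA + Doxy against tTA, 5 (3 higher, 2 lower), it was 10 (7 and 3) with the median scaling, 11 (8 and 3) with no further normalization, 2 with all probe sets, 11 with array weights, 3 without tTA 9310 and 9322 and 2 without tTA 7288 and tTA + Doxy 7399. For the interaction, 1 (lower), it was 6 (5 higher, 1 lower) with the median scaling, 6 (5 higher, 1 lower) with no further normalization, 0 with all probe sets, 5 with the brightest 40%, 4 without tTA 9310 and 9322 and 0 without tTA 7288 and tTA + Doxy 7399. With each array left out in turn these counts ran from 54 to 240, 241 to 493, 1 to 7, 3 to 23 and 0 to 4. The lists, 8, 6, 7, 7 and 3 in that order, numbered 3, 1, 0, 0 and 0 with the estimated correlation and 8, 3, 0, 0 and 2 with fry. In tTA against FVBN control fry called the atrial list (adjusted p = 0.0088) and not the proteasome list (0.362). The called members of the atrial list were Clu and Stard10 (0.31 ± 0.07), both higher. In tTA + Doxy against FVBN + Doxy it called calcium handling, ion channels and the proteasome list (0.00906 for the last). In the interaction it called the proteasome list (0.0155) and mitochondrial translation (0.0123). The beta-actin ratio as a covariate gave 3 lists by camera in tTA + Doxy against FVBN + Doxy. With the median scaling FVBN + Doxy against FVBN control had 11 and the interaction 8, and with no further normalization 13 and 7. With each array left out the lists ran from 5 to 9 in tTA against FVBN control, 4 to 8 in FVBN + Doxy against FVBN control, 3 to 9 in tTA + Doxy against tTA and 3 to 5 in the interaction, the lowest without FVBN control array 8182 (5), FVBN control array 8177 (4) and tTA + Doxy array 7424 (3). The correlation of the tTA effects was 0.433 with the brightest 40%, 0.172 with the Xist level and 0.539 with the beta-actin ratio, and 0.275 to 0.429 with each array left out; that of the Doxy effects was -0.204 with the Xist level and -0.0336 with the beta-actin ratio, and -0.213 to -0.0435 with each array left out.

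Values that changed sign belonged to other probe sets or to genes within error of 0. Other probe sets stood at -0.059 (tTA against FVBN control) and -0.082 (under Doxy) for Tpm2 and 0.030 for Itpr2, all too dim to be tested, and at -0.037 for Aqp1, 0.013 for Gstm5 in tTA + Doxy against tTA, and -0.039 (tTA + Doxy against tTA) and -0.014 (interaction) for Myh7. In tTA against FVBN control, Atp2a2 was 0.055 with the Xist level and -0.27 to 0.13 with each array left out. In tTA + Doxy against FVBN + Doxy, Myh7 was 0.0044 with the median scaling and 0.00028 with the Xist level, and -0.19 to 0.074 with each array left out. In FVBN + Doxy against FVBN control, Myh6 was 0.0066 with array weights and 0.0044 with the beta-actin ratio, and -0.022 to 0.010 with each array left out, and Atp2a2 was 0.14 with the Xist level and -0.21 to 0.19. In tTA + Doxy against tTA, Acta1 was 0.0036 with the median scaling, 0.042 with the beta-actin ratio and 0.00089 without tTA 7288 and tTA + Doxy 7399, and -0.16 to 0.086 with each array left out. There Nppa was 0.0074 without tTA 9310 and 9322 (-0.12 to 0.0061), Nppb -0.031 with the Xist level and -0.094 without tTA 9310 and 9322 (-0.11 to 0.12), and Myh7 -0.097 with array weights and -0.0013 with the beta-actin ratio (-0.15 to 0.096). Atp2a2 there was 0.0052 with array weights, 0.0040 without tTA 9310 and 9322 and 0.0061 without tTA 7288 and tTA + Doxy 7399 (-0.038 to 0.031). In the interaction, Atp2a2 was 0.079 with the median scaling, 0.058 with no further normalization, 0.0076 with array weights, 0.015 without tTA 9310 and 9322, 0.0071 with the beta-actin ratio and 0.018 without tTA 7288 and tTA + Doxy 7399 (-0.20 to 0.20). For these genes the cause was not tested.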

Other observations

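The test of liver RNA was chosen only after the result was seen. Mup3, a major urinary protein gene made mainly in liver, read 7.86 in tTA array 7311 and 6.529 in tTA array 7308, against 5.425 and 5.572 in the FVBN control arrays. Liver RNA in the sample could do this, and 16 of 20 liver markers had a probe set to look at. Their median in array 7311 was 0.14 above the other tTA arrays (upper quartile 0.261), and 16 of 16 were higher there. Among them Cyp3a11, Fgg and Fgb could not be lower, since their mean in the other tTA arrays was the floor, 3.845. The largest differences were those of Alb, the albumin gene (1.54), Cyp3a11 (0.595, with a mean of 3.845, the floor, in the other tTA arrays), Cps1 (0.393), Arg1 (0.299) and Apoa2 (0.248). A trace of liver RNA and a change of single genes cannot be told apart, because a trace of liver may lie below what dim markers can show (median 0.14). A Mup3 and Alb assay on the remaining RNA of this sample would decide. Antigen presentation genes varied within each group: H2-K1 ran from 9.539 to 10.81 among tTA arrays and from 10.2 to 10.93 among tTA + Doxy arrays, and Cd74, the invariant chain, from 7.632 to 9.494 among tTA arrays.

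The array without a group had these log2 values: Clu 8.64, Tpm2 6.455, Gstm5 9.428, Acta1 9.60, Ryr2 9.405, Gja1 10.85 and Iigp1, an interferon-induced GTPase, 10.28, with a beta-actin ratio of 0.529.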
